A study of Homo sapiens with 24 samples.

How the data were processed

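RNA of MHH-CALL4 and MUTZ-5 cells was measured on 12 Affymetrix arrays that cover the exons of human genes, with 3 arrays for each of the 4 groups made by 2 cell lines and DMSO or JQ1. The deposited values are RMA log2 values, which the authors made in Affymetrix Expression Console by background correction, quantile normalization and summary of probes over each transcript cluster (the array's unit for a gene). The program's version, the genome build and the set of arrays normalized together are not stated. Each array was deposited in 2 forms, giving 24 columns: summarised over the core probe set list, and over the extended probe set list. Both forms come from the same scan and count as 1 replicate. The files give no detection calls and no background level, so signal over background is not known. The labels do not say whether the 3 samples of a group were separate cultures, and p-values measure the spread between these samples, which may be technical. No scan dates were used here, so scan batches could not be compared.

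The core form holds 22011 transcript clusters and the extended form 133672. Gene symbols came from the array annotation supplied with the series and were brought up to date through RefSeq gene IDs (GRCh38.p14, used only for names and for which genes neighbour each other). Of the annotated clusters 19907 matched a RefSeq gene, and the update changed 0 symbols of the core set. Of the core clusters, 14432 carry 1 symbol, 2408 carry several and 5171 are not in the annotation. Only clusters with 1 symbol were used, and for the 197 genes with more than 1 such cluster the one with the highest mean over the 12 arrays was taken, which leaves 14232 genes. CRLF2 is not among them and was not analysed here. No filter on low values and no further normalization were applied.

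A linear model with 1 mean per group was fitted to the 12 core arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings). Contrasts were JQ1 minus DMSO in each line, the difference of these effects (MUTZ-5 minus MHH-CALL4), their mean, and MUTZ-5 minus MHH-CALL4 under DMSO. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and a change of at least 2-fold is an absolute log2 difference of at least 1. All tests were two-sided. Group values are the mean ± SD of 3 arrays in log2 units.

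Gene lists, 30 in all, were written from general knowledge, of which 1 is not used here. The others are: MYC targets, RNA polymerase I and III subunits, interleukin-7 receptor and JAK-STAT components, STAT5 targets, histones, P-TEFb with 7SK and super elongation complex, markers of BET inhibitor exposure, BCL2 family, G1 regulators, DNA replication, mitosis, p53 targets, B lineage transcription factors, B cell receptor and precursor B cell genes, MHC class II, interferon-stimulated genes, NF-kappaB targets, cholesterol biosynthesis, immediate early genes, integrated stress response, lysosome and autophagy, ribosomal proteins, glycolysis, Ph-like classifier genes, and markers of T and NK cells, myeloid cells, erythroid cells and megakaryocytes, stroma, and plasma cells. Some genes stand in several lists. Each list was tested against all other genes with limma camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists of a comparison. The same test was run with a correlation estimated for each list, and fry tested whether a list's genes moved one way without comparison to other genes. Members were also adjusted over the list alone.

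The lists, the tests, most alternatives and the rule for naming genes were fixed before the data were examined. The rule names MYC and IL7R; the 8 largest increases and decreases in each line among called genes whose 3 JQ1 and 3 DMSO values do not overlap and whose higher group mean reaches the median of all genes (8.52); up to 4 called members of each list, or 2 where none passed; the 5 largest differences between lines each way; the 6 largest each way under DMSO; and BRD2, BRD3, HEXIM1, JAK2, CDKN1A, BCL2 and SERPINI1. Passed over in the choice of the largest changes, and only counted, were XIST, genes on chromosome Y, immunoglobulin and T cell receptor segments, and open reading frames, antisense and other RNA genes, and symbols that start with LOC. These are 454 genes, of which 69 were called in MHH-CALL4 and 40 in MUTZ-5, so the largest changes are those among the other genes. Not all genes the rule reaches are discussed.

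The procedure was tested on simulated data drawn from each gene's DMSO mean and residual SD, with known changes added to some genes. In MHH-CALL4 59.7% of effects of 0.5 log2, 98.6% of effects of 1 and 100.0% of effects of 2 were recovered, with 7 false calls among 181 calls. In MUTZ-5 the recovered shares were 78.4%, 95.5% and 98.3%, with 9 false calls among 189. For the difference between lines they were 35.2%, 85.3% and 98.8%, with 6 false calls among 161. Genes were drawn independently of each other here and few were changed. In the real arrays residuals moved together, with 43.9% of the residual variance on 1 axis, and within each line far more genes were called. These shares and false calls therefore do not give the error rates of the real data.

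Alternatives were the extended summaries, median centring and cyclic loess between arrays, genes at or above the median level only, another eBayes prior (trend and robust), fits to the compared arrays alone, array weights, the replicate number as a block, the mean of a gene's clusters, all core clusters, leaving out each array, and estimated correlation or fry for the lists. Leaving out the 2 arrays farthest along the main axis of residual variation, and using that axis as a covariate, were chosen after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.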

Results

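MHH-CALL4 and MUTZ-5 are established human cell lines of B cell precursor acute lymphoblastic leukemia. JQ1 is a small molecule that displaces BET bromodomain proteins from acetylated chromatin, and DMSO is its solvent. Cells of each line received 500 nM JQ1 or DMSO for 8 hours, and RNA of 3 samples per group was measured on 1 array each, 12 arrays in all. The median of the 14232 genes used lay between 8.46 and 8.57 log2 units in every array. The number of arrays limits the precision of each value. The first principal component, with 55.9% of the variance, parted the lines and the second, with 25.8%, parted JQ1 from DMSO. Within groups, MUTZ-5 DMSO replicate 3 and MHH-CALL4 JQ1 replicate 3 stood at opposite ends of the main axis of residual variation, with scores of -0.55 and 0.47. This axis held 43.9% of the residual variance.

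**Figure D1:**
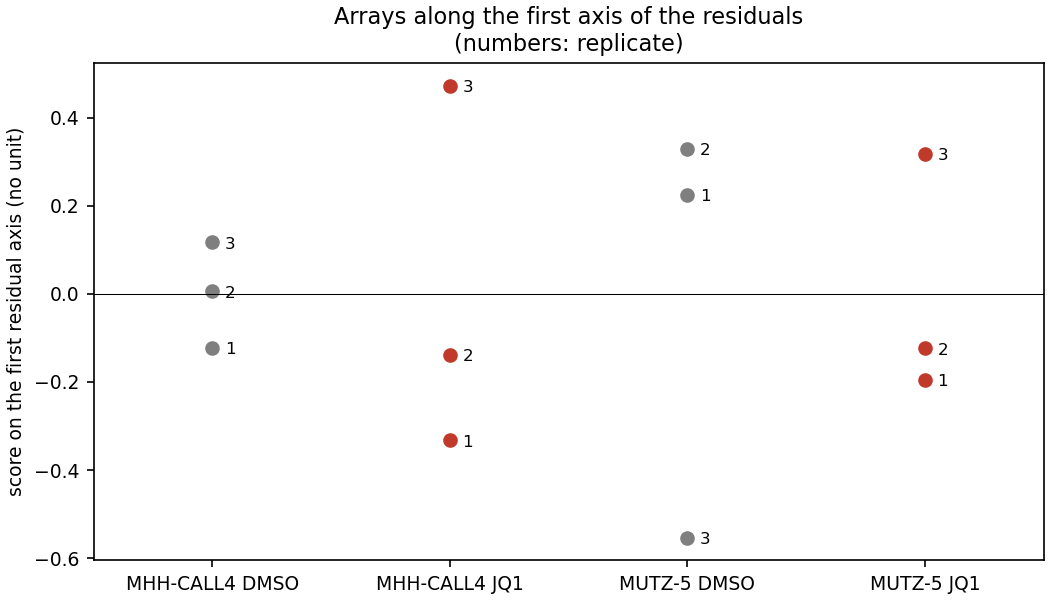
Score of each of the 12 arrays on the main axis of residual variation (43.9% of the residual variance), by group. MUTZ-5 DMSO replicate 3 (-0.55) and MHH-CALL4 JQ1 replicate 3 (0.47) lie farthest from 0.

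The comparison of JQ1 with DMSO in each line asks which genes respond to BET inhibition, and the study is known for MYC and IL7R. MYC, a transcription factor that drives growth, fell in MHH-CALL4 from 12.51 ± 0.038 under DMSO to 10.46 ± 0.079 under JQ1 (log2, mean ± SD, n = 3). This is a 4.15-fold decrease (limma, SE 0.068, adjusted p = 8.6e-10). In MUTZ-5 MYC fell from 12.65 ± 0.056 to 11.33 ± 0.035, a 2.50-fold decrease (adjusted p = 5.3e-08). IL7R, which encodes the interleukin-7 receptor chain that precursor B cells use for survival signals, fell 3.89-fold in MHH-CALL4, from 11.62 ± 0.066 to 9.66 ± 0.20 (adjusted p = 6.2e-08). In MUTZ-5 it fell 4.57-fold, from 11.40 ± 0.11 to 9.21 ± 0.20 (adjusted p = 5.5e-08). The plot of these genes by array shows every JQ1 value of MYC and IL7R below every DMSO value of its line. MYC values under DMSO were 12.56, 12.48 and 12.50 in MHH-CALL4 and 12.65, 12.59 and 12.70 in MUTZ-5, and under JQ1 10.51, 10.50 and 10.37 and 11.35, 11.29 and 11.34. IL7R values under DMSO were 11.67, 11.65 and 11.55 in MHH-CALL4 and 11.33, 11.34 and 11.53 in MUTZ-5, and under JQ1 9.88, 9.63 and 9.48 and 9.36, 9.28 and 8.99.

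**Figure D2:**
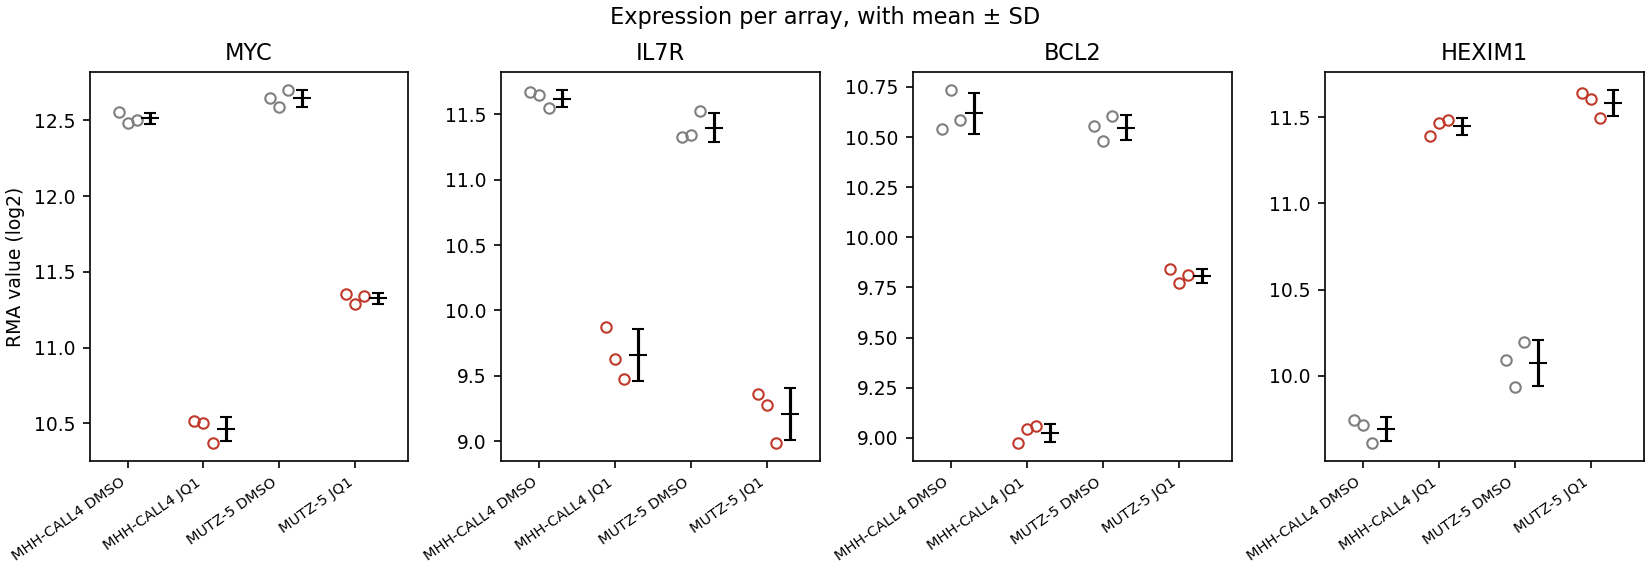
RMA log2 values of MYC, IL7R, BCL2 and HEXIM1 in each of the 12 arrays, by cell line and treatment, with the mean and SD of 3 arrays as bars; each panel has its own axis. JQ1 values of MYC, IL7R and BCL2 lie below the DMSO values of the same line, and those of HEXIM1 above them.

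In MHH-CALL4 the largest fall was that of GSDME, which encodes the pore-forming protein gasdermin E, from 11.89 ± 0.069 to 8.46 ± 0.085 (10.8-fold, SE 0.086 log2, n = 3, limma adjusted p = 6.9e-11). SCIMP, a signalling adaptor, fell 10.6-fold and PECAM1, an adhesion molecule, 6.60-fold. Over the alternatives GSDME ranged from -3.48 to -2.57 log2 and SCIMP from -3.44 to -3.09, so the order of these 2 genes depends on the processing. IL1B, the cytokine interleukin-1 beta, fell 6.38-fold (1.78 log2 with extended summaries) and MPO, the neutrophil enzyme myeloperoxidase, 5.54-fold. The anti-apoptotic gene BCL2 fell by 1.59 log2 (3.02-fold). The largest increases were those of the histone gene H2BC11 (2.21 log2), the epoxide hydrolase EPHX1 (1.82, and 1.19 with extended summaries), the protein kinase A subunit PRKAR2B (1.81), H4C8 (1.77) and HEXIM1 (1.76), which encodes an inhibitor of the elongation kinase P-TEFb. SAT1, an enzyme of polyamine breakdown, rose by 1.61 log2. In these genes all 3 JQ1 values lay beyond all 3 DMSO values. Of 14232 genes, 4057 were called, 1563 higher and 2494 lower under JQ1. At least 2-fold changes were found in 286 genes, of which 59 rose and 227 fell. Groups did not overlap in 43.8% of genes, where chance gives 10%. Decreases were 61.5% of all calls as deposited and 51.5% after median centring of the arrays (2162 higher, 2293 lower), and 56.0% after cyclic loess (1972 higher, 2512 lower). They were 79.4% of the changes of at least 2-fold as deposited.

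With the preset correlation the lists of MYC targets, polymerase I and III, integrated stress response and DNA replication genes lay below other genes in MHH-CALL4. Of 52 measured MYC target genes 43 fell, 1 rose and 8 did not pass (46 lower and 1 higher adjusted over the list alone), with a median of -0.65 log2. EXOSC5, a subunit of the RNA exosome, fell by 1.56 log2, POLR1B by 1.49, the mitochondrial coactivator PPRC1 by 1.45 and the ribosome assembly factor UTP20 by 1.36. The list lay below other genes (camera adjusted p = 4.6e-22; adjusted p = 0.231 with an estimated correlation). Of 15 subunits and factors of RNA polymerases I and III 10 fell and 5 did not pass (11 lower adjusted over the list alone), among them POLR1A (-0.99), POLR3D (-0.76) and UBTF (-0.66). Their median was -0.53 log2 (camera adjusted p = 8.9e-06; adjusted p = 0.368 with an estimated correlation). Integrated stress response genes, which serve amino acid supply, fell in 17 of 26 cases, rose in 2 and did not pass in 7 (19 lower and 4 higher adjusted over the list alone). The cystine transporter SLC7A11 fell by 1.85 log2, the serine synthesis enzyme PSAT1 by 1.65 and the arginine transporter SLC7A1 by 1.54. The list's median was -0.41 (camera adjusted p = 8.9e-06; adjusted p = 0.368 with an estimated correlation). Of 34 DNA replication genes 13 fell, 1 rose and 20 did not pass, with the same counts adjusted over the list alone. MCM2 fell by 0.68 log2 and POLE2 by 0.61, whereas TK1 rose by 0.52 (median -0.16, camera adjusted p = 0.0039; adjusted p = 0.634 with an estimated correlation). Among genes at or above the median level the call for DNA replication was lost (adjusted p = 0.111) with the median at -0.16.

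With that correlation 6 further lists lay below other genes in MHH-CALL4. Of 21 STAT5 target genes 13 fell, 2 rose and 6 did not pass, also when adjusted over the list alone. CCND2, a cyclin of the G1 phase, fell by 1.40 log2, and IKZF4 (-1.21), the survival gene BCL2L1 (-0.75) and the feedback inhibitor CISH (-0.74) fell too (list median -0.37, camera adjusted p = 8.0e-04; adjusted p = 0.368 with an estimated correlation). Of 34 B lineage transcription factors 18 fell, 3 rose and 13 did not pass, also when adjusted over the list alone, with falls of 1.36 in ERG, 1.16 in IKZF2, 1.08 in IKZF3 and 0.98 in IKZF1. Their median was -0.34 (camera adjusted p = 9.6e-05; adjusted p = 0.368 with an estimated correlation). Of 29 B cell receptor and precursor B cell genes 10 fell and 19 did not pass (10 lower and 1 higher adjusted over the list alone), including CD72 (-1.68), the surrogate light chain VPREB1 (-1.03), BANK1 (-1.003) and the kinase SYK (-0.84). This list's median was -0.099 (camera adjusted p = 0.0046; adjusted p = 0.497 with an estimated correlation). Of 9 MHC class II genes 6 fell and 3 did not pass (7 lower adjusted over the list alone), with the class II transactivator CIITA at -0.71 and RFX5 at -0.56 (median -0.29, camera adjusted p = 0.0076; adjusted p = 0.497 with an estimated correlation). Of 13 plasma cell markers 4 fell and 9 did not pass (5 lower adjusted over the list alone), with FKBP11 at -0.84 and DERL3 at -0.67 (median -0.22, camera adjusted p = 0.013; adjusted p = 0.368 with an estimated correlation). Of 33 interferon-stimulated genes 9 fell, 4 rose and 20 did not pass (11 lower and 5 higher adjusted over the list alone), with IFITM1 at -1.23, OAS2 at -1.07 and OAS3 at -1.05. Their median was -0.20 (camera adjusted p = 0.039; adjusted p = 0.634 with an estimated correlation). The interferon call was lost without MHH-CALL4 DMSO replicate 2 (adjusted p = 0.0882) and without MHH-CALL4 JQ1 replicate 3 (adjusted p = 0.0622). Among genes at or above the median level the calls were lost for the B cell receptor, class II, plasma cell and interferon lists, with adjusted p of 0.0508, 0.0769, 0.0508 and 0.412 and medians of -0.15, -0.29, -0.23 and -0.18. After median centring the B cell receptor median was -0.057.

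The lists of histone, immediate early, and lysosome and autophagy genes lay above other genes in MHH-CALL4 with the preset correlation. Of 14 histone genes 7 rose and 7 did not pass, also when adjusted over the list alone, led by H2BC11, H4C8, H2BC5 (1.71) and H2BC21 (1.42), with a median of 0.31, and 0.87 with extended summaries (camera adjusted p = 1.2e-05; adjusted p = 0.368 with an estimated correlation). Histone genes are near copies of each other, so a probe set can read more than 1 of them. Of 27 immediate early genes, which respond to stimuli within minutes, 8 rose, 2 fell and 17 did not pass (9 higher and 2 lower adjusted over the list alone). JUN rose by 0.84, JUND by 0.70 and IER3 by 0.53, and MYC, also a member, fell (median 0.13, camera adjusted p = 0.015; adjusted p = 0.368 with an estimated correlation). This call was lost without MHH-CALL4 JQ1 replicate 3 (median 0.085, adjusted p = 0.0699). The median was 0.072 without DMSO replicate 1 and 0.21 among genes at or above the median level. Of 27 lysosome and autophagy genes 11 rose, 4 fell and 12 did not pass, also when adjusted over the list alone, with CTSK at 1.16, the sialidase NEU1 at 1.03, MAP1LC3B at 0.64 and CTSS at -0.75. The median was 0.17 (camera adjusted p = 0.0083; adjusted p = 0.539 with an estimated correlation).

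Several lists central to the treatment were not called in MHH-CALL4, and most of them had members that moved each way. Of 17 interleukin-7 receptor and JAK-STAT components 5 fell, 3 rose and 9 did not pass (camera adjusted p = 0.541), with the same counts adjusted over the list alone. The phosphatase PTPN6 fell by 1.49 and STAT6 by 0.51, STAT3 rose by 0.48, and JAK2 differed by -0.0084 (adjusted p = 0.966). Of 16 BCL2 family members 5 fell, 2 rose and 9 did not pass (6 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.222), with PMAIP1 at -0.85 and the pro-apoptotic BCL2L11 at 0.69. Of 20 G1 regulators 6 fell, 2 rose and 12 did not pass, also when adjusted over the list alone, with CDK6 at -0.73 (camera adjusted p = 0.223). Of 18 members of P-TEFb, 7SK and the super elongation complex 5 rose, 3 fell and 10 did not pass, also adjusted over the list alone, with ELL2 at 1.19 and NELFCD at -0.90 (camera adjusted p = 0.416). BRD2 rose by 0.30 (adjusted p = 0.014), a call lost without MHH-CALL4 DMSO replicate 2 (adjusted p = 0.0513) and without JQ1 replicate 1 (adjusted p = 0.0571), and BRD3 differed by -6.0e-04 (adjusted p = 0.996). Of 20 markers of BET inhibitor exposure 5 rose, 8 fell and 7 did not pass, also adjusted over the list alone (camera adjusted p = 0.376). The estimated correlation gave no call for any of these lists. Fry, which does not compare a list with other genes, called 4 lists lower. These were BET inhibitor markers (adjusted p = 5.36e-05), BCL2 family (0.000177), G1 regulators (0.00165) and JAK-STAT components (0.00544). It did not call the elongation list (fry adjusted p = 0.211). Signs of median, mean and test differed for p53 targets and for the T and NK cell, myeloid and stromal markers.

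**Figure D3:**
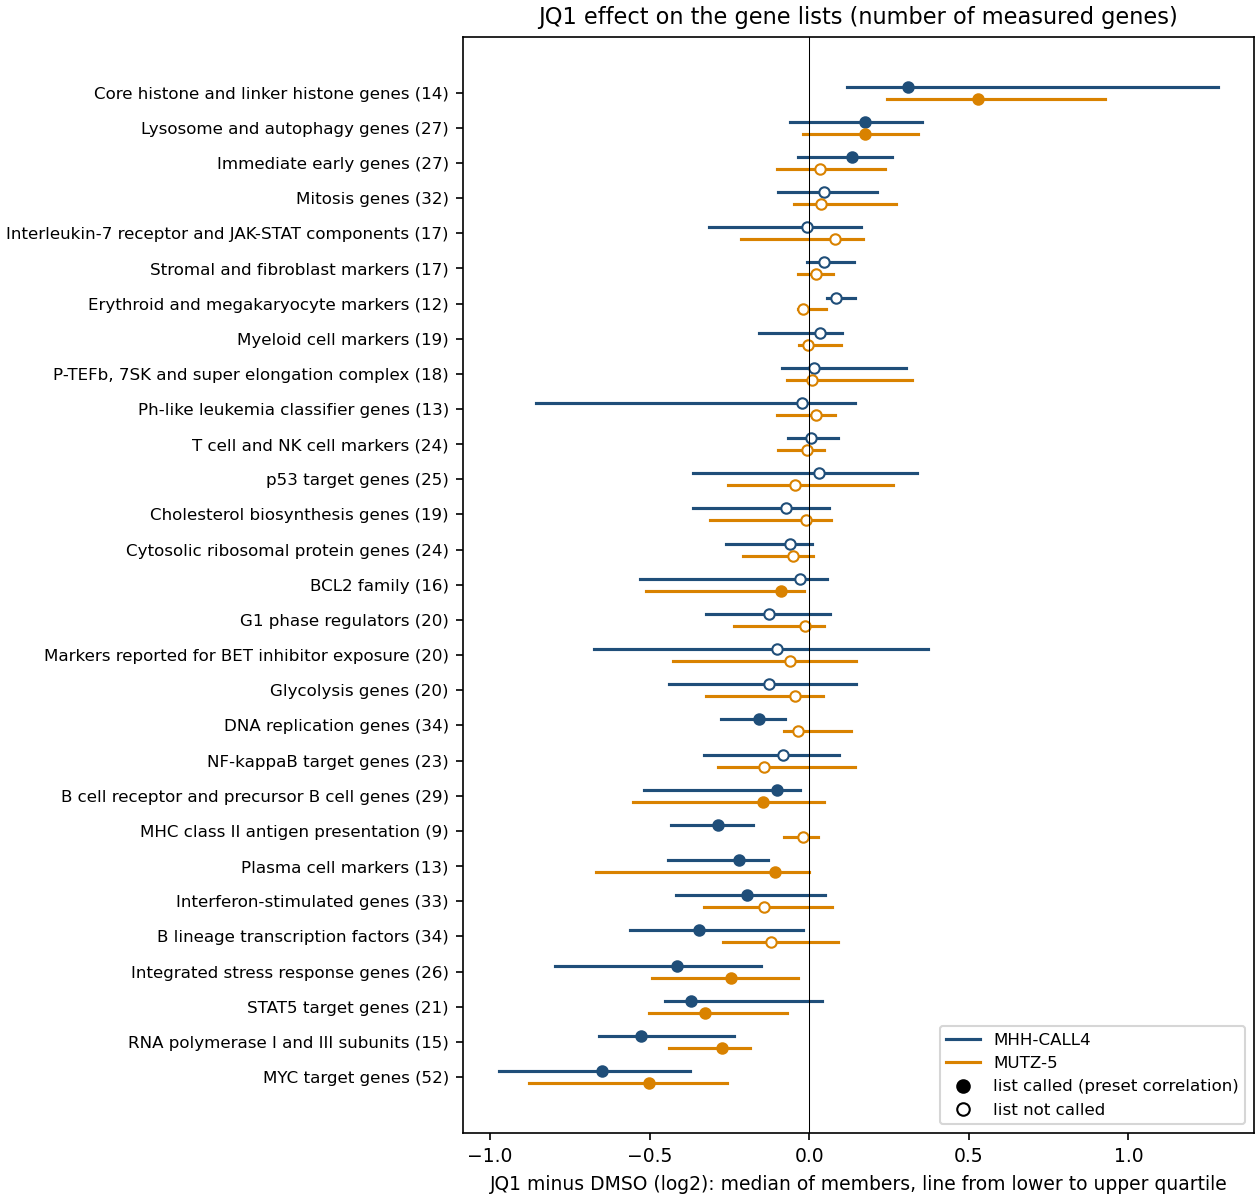
Median JQ1 minus DMSO difference (log2) of each gene list described in MHH-CALL4 and MUTZ-5, with the quartiles of the members as bars. Filled points mark lists called at adjusted p under 0.05 with the preset correlation of 0.01, and with an estimated correlation 0 lists were called in either line.

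In MUTZ-5 the largest fall was that of CCL2, a chemokine that attracts monocytes, from 10.40 ± 0.077 to 7.74 ± 0.24 (6.34-fold, n = 3, limma adjusted p = 4.6e-08). The integrin ITGA8 fell 6.21-fold, from 9.08 ± 0.17 to 6.44 ± 0.048, and CHI3L2, a chitinase-like protein, 5.09-fold. Under JQ1 ITGA8 lay near the low end of the scale, so the size of its fall is not exact. With extended summaries CCL2 fell by 1.74 log2 and CHI3L2 by 1.39. ITGA8 ranged from -2.71 to -2.35 log2 over the alternatives, so the first rank of CCL2 depends on the processing. GSDME fell 4.76-fold, the retinoic acid hydroxylase CYP26A1 4.67-fold and the gap junction gene GJB6 4.56-fold. BCL2 fell by 0.74 log2. Among the largest increases were those of PRKAR2B (2.45 log2), FGD6 (2.36), SERPINI1 (2.24), which encodes neuroserpin, EPHX1 (1.59, and 0.91 with extended summaries), GLCE (1.54) and HEXIM1 (1.51). In these genes all 3 JQ1 values lay beyond all 3 DMSO values. Under DMSO PRKAR2B, FGD6 and SERPINI1 lay at 6.12, 6.75 and 6.42 in MUTZ-5, near the low end of the scale. The size and order of their rises are therefore not exact. Of 14232 genes 3138 were called, 1290 higher and 1848 lower under JQ1. Changes of at least 2-fold were found in 230 genes, of which 56 rose and 174 fell. With extended summaries they were found in 144 genes, of which 36 rose and 108 fell. Groups did not overlap in 32.6% of genes, where chance gives 10%. Decreases were 58.9% of all calls as deposited, 48.5% after median centring (1761 higher, 1656 lower) and 55.6% after cyclic loess (1659 higher, 2080 lower). They were 47.3% without MUTZ-5 DMSO replicate 3 (1673 higher, 1502 lower) and 68.2% without DMSO replicate 2 (900 higher, 1930 lower). They were 75.7% of changes of at least 2-fold.

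In MUTZ-5 the lists of MYC targets, polymerase I and III and integrated stress response genes lay below other genes with the preset correlation. Of 52 MYC target genes 37 fell, 1 rose and 14 did not pass (42 lower and 1 higher adjusted over the list alone), with POLR1B at -1.48, PPRC1 at -1.46, EXOSC5 at -1.20 and UTP20 at -1.14. The median was -0.50 log2 (camera adjusted p = 9.0e-22; adjusted p = 0.239 with an estimated correlation). Of 15 polymerase I and III genes 8 fell, 1 rose and 6 did not pass (10 lower and 1 higher adjusted over the list alone), with POLR1A at -0.74, POLR3D at -0.70 and POLR3E at -0.45. Their median was -0.27, with -0.18 without MUTZ-5 DMSO replicate 3 and -0.43 among genes at or above the median level (camera adjusted p = 3.5e-04; adjusted p = 0.51 with an estimated correlation). Of 26 integrated stress response genes 14 fell, 2 rose and 10 did not pass (15 lower and 2 higher adjusted over the list alone). SLC7A11 fell by 2.07, PSAT1 by 1.66, the leucine transporter SLC7A5 by 1.35 and SLC7A1 by 1.31 (median -0.25, camera adjusted p = 1.5e-05; adjusted p = 0.51 with an estimated correlation). DNA replication genes did not shift as a list, with 5 lower, 4 higher and 25 of 34 not past the test (5 lower and 5 higher adjusted over the list alone; camera adjusted p = 0.945).

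The lists of STAT5 targets, B cell receptor and precursor B cell genes, BCL2 family members and plasma cell markers also lay below other genes in MUTZ-5 with the preset correlation. Of 21 STAT5 targets 12 fell, 1 rose and 8 did not pass (13 lower and 1 higher adjusted over the list alone), with CCND2 at -1.22, DUSP6 at -1.21, CISH at -1.14 and IKZF4 at -1.10. The median was -0.33 (camera adjusted p = 1.5e-05; adjusted p = 0.407 with an estimated correlation). Of 29 B cell receptor and precursor B cell genes 13 fell, 2 rose and 14 did not pass (14 lower and 2 higher adjusted over the list alone), with CD72 at -1.51 (-0.98 with extended summaries), VPREB1 at -1.09, VPREB3 at -1.01 and the progenitor antigen CD34 at -0.95. Their median was -0.14 (camera adjusted p = 0.0017; adjusted p = 0.51 with an estimated correlation). Of 16 BCL2 family members 5 fell, 1 rose and 10 did not pass, also adjusted over the list alone, with BCL2L1 at -1.001, PMAIP1 at -0.95 and BID at -0.63. The median was -0.088 (camera adjusted p = 0.022; adjusted p = 0.51 with an estimated correlation). Of 13 plasma cell markers 6 fell and 7 did not pass, also adjusted over the list alone, with TNFRSF17, the receptor BCMA, at -1.53, FKBP11 at -0.92 and PRDM1 at -0.88 (median -0.11, camera adjusted p = 0.014; adjusted p = 0.407 with an estimated correlation). Among genes at or above the median level the calls for the BCL2 family and plasma cell markers were lost (adjusted p = 0.101 and 0.227) with medians of -0.11 and -0.25. After median centring these medians were -0.042 and -0.060, and the plasma cell median was -0.18 without MUTZ-5 DMSO replicate 1. Histone genes rose in 9 of 14 cases and 5 did not pass (11 higher adjusted over the list alone), with H2BC5 at 1.43, H2BC21 at 1.36, H2BC11 at 1.20 (0.76 with extended summaries) and H2AJ at 0.98. Their median was 0.53 (camera adjusted p = 9.3e-08; adjusted p = 0.407 with an estimated correlation). Of 27 lysosome and autophagy genes 10 rose, 3 fell and 14 did not pass (10 higher and 4 lower adjusted over the list alone), with NEU1 at 0.99, CTSK at 0.57, CTSB at 0.55 and CTSS at -0.56 (median 0.17, camera adjusted p = 0.011; adjusted p = 0.627 with an estimated correlation).

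Lists without a call in MUTZ-5 included B lineage transcription factors, of which 10 fell, 4 rose and 20 did not pass (10 lower and 5 higher adjusted over the list alone), with IKZF3 at -1.01 and BCL11A at -0.73 (camera adjusted p = 0.141). None of 9 MHC class II genes passed, also adjusted over the list alone (camera adjusted p = 0.933), and HLA-DMB and RFX5 differed by 0.17 and -0.26. Of 33 interferon-stimulated genes 9 fell, 3 rose and 21 did not pass (10 lower and 4 higher adjusted over the list alone), with TRIM22 at -1.13, IFITM1 at -1.10 and IRF7 at 0.80 (camera adjusted p = 0.057). The interferon list passed without MUTZ-5 DMSO replicate 1 or 2 or JQ1 replicate 1 or 2 (adjusted p from 0.0187 to 0.0453), with extended summaries (adjusted p = 0.016) and after median centring (adjusted p = 0.034). Of 17 interleukin-7 receptor and JAK-STAT components 4 fell, 4 rose and 9 did not pass (5 lower and 4 higher adjusted over the list alone), with PTPN6 at -1.16, JAK1 at 0.63 and STAT3 at 0.58 (camera adjusted p = 0.964). JAK2 differed by 0.16 (adjusted p = 0.366). Immediate early genes rose in 7 cases, fell in 5 and did not pass in 15 (8 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.784). Of 20 G1 regulators 6 fell, 1 rose and 13 did not pass (6 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.274), with CCND1 at -0.90 (-0.52 with extended summaries) and CDK6 at -0.47. CDKN1A, the inhibitor p21, fell by 0.23 (adjusted p = 0.048), a call lost without DMSO replicate 1 or 3 or JQ1 replicate 2 or 3 of that line (adjusted p from 0.0902 to 0.192). It was also lost with extended summaries (-0.14, adjusted p = 0.24), after median centring (adjusted p = 0.0826) and with only the groups compared (adjusted p = 0.114). CDKN1A differed by 0.032 in MHH-CALL4 (adjusted p = 0.801). Of 18 elongation factors 5 rose, 3 fell and 10 did not pass, also adjusted over the list alone, with HEXIM2 at -0.58 and, with extended summaries, -0.37 (camera adjusted p = 0.487). BRD2 rose by 0.37 (adjusted p = 0.0050), and BRD3 differed by 0.061 (adjusted p = 0.659). Of 20 BET inhibitor markers 5 rose, 6 fell and 9 did not pass (5 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.814). Fry called G1 regulators (adjusted p = 0.00492), B lineage transcription factors (0.0121) and interferon-stimulated genes (0.0158) lower in MUTZ-5. It did not call the other lists of this paragraph. Signs of median, mean and test differed for DNA replication, JAK-STAT, Ph-like, immediate early, erythroid and stromal lists.

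Markers of other blood and stromal cells had no camera list call in either line with all arrays. Of these lists fry called only the myeloid one, lower in MHH-CALL4 (fry adjusted p = 0.00544). Of 24 T and NK cell markers 4 fell in MHH-CALL4 (adjusted p = 0.616) and 3 in MUTZ-5 (adjusted p = 0.342), also adjusted over the list alone, with the kinases ZAP70 (-0.98 and -1.13) and LCK (-0.91 and -1.38) in both. Without MUTZ-5 DMSO replicate 3 the T and NK list passed in MUTZ-5 (adjusted p = 0.0387). Of 19 myeloid markers MPO, CTSG (-1.35), VCAN (-0.85, and -0.46 with extended summaries) and LYZ (-0.83) fell and 1 rose in MHH-CALL4 (4 lower and 2 higher adjusted over the list alone; adjusted p = 0.376). In MUTZ-5 VCAN (-1.58) and MPO (-0.48) fell, also adjusted over the list alone (adjusted p = 0.933). Of 12 erythroid and megakaryocyte markers 1 rose in MHH-CALL4 and none passed in MUTZ-5, also adjusted over the list alone (adjusted p = 0.376 and 0.933). Of 17 stromal markers 1 fell in MHH-CALL4, and 1 rose and 2 fell in MUTZ-5, also adjusted over the list alone (adjusted p = 0.594 and 0.933), with PDGFRB at -0.85 and -0.66.

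The same treatment in both lines allows their responses to be set side by side. MYC, IL7R, GSDME, BCL2, CD72, PSAT1 and SLC7A11 fell and HEXIM1, PRKAR2B and EPHX1 rose in each line. In all 2324 genes were called in the same direction in both, 817 higher and 1507 lower, where independent calls would give 141.7 and 323.8. Opposite calls were made for 21 genes. After median centring the shared calls were 1140 higher and 1371 lower, and after cyclic loess 1211 and 1634. Of the 4850 genes called in either line 91.7% had the same sign in both. Across all genes, which are not independent replicates, the log2 differences of the lines correlated with Pearson r = 0.767 and Spearman rho = 0.690. On average over the lines 5136 genes were called, 2164 higher and 2972 lower, and after median centring 3182 were higher and 2629 lower, whereas after cyclic loess 2594 were higher and 3044 lower. Changes of at least 2-fold on average were found in 225 genes.

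**Figure D4:**
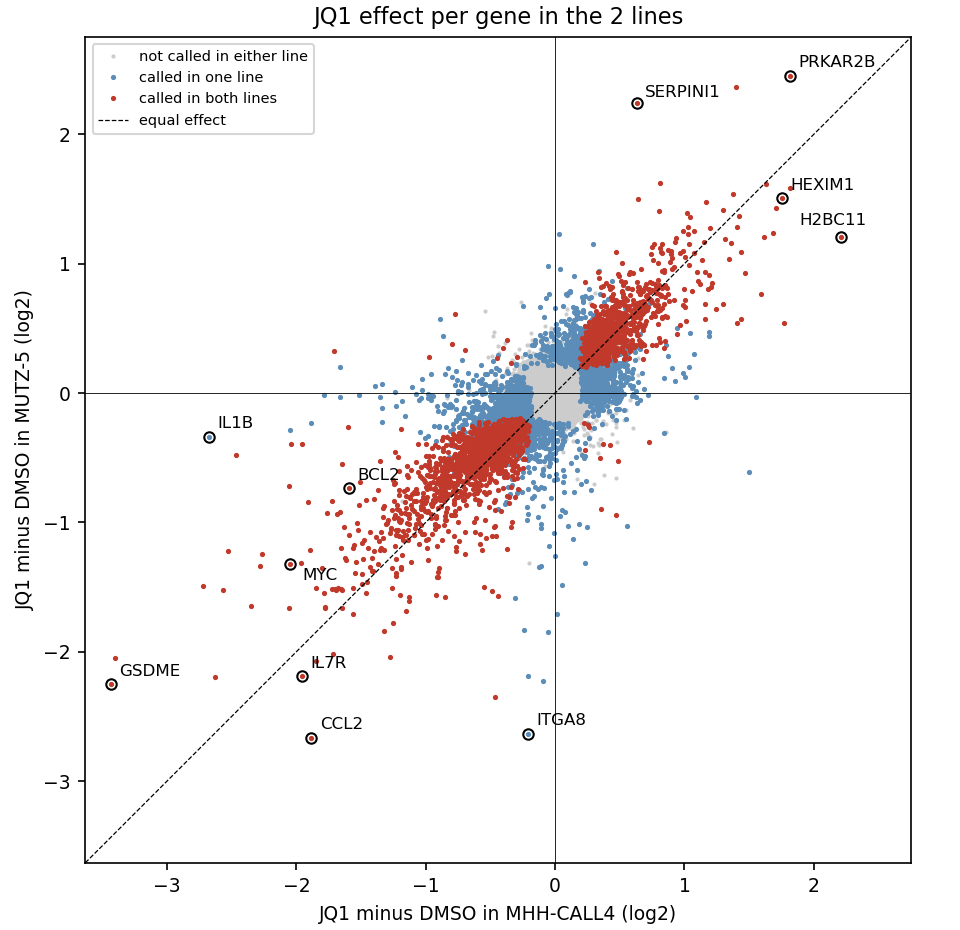
JQ1 minus DMSO difference (log2) of each of 14232 genes in MHH-CALL4 (x axis) and MUTZ-5 (y axis). Grey points were not called, blue points were called in 1 line and red points in both; the points follow the diagonal with Pearson r = 0.767.

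The difference between the lines' responses was tested directly for each gene. MYC fell further in MHH-CALL4 by 0.73 log2 (SE 0.097, n = 3 arrays per group, limma adjusted p = 0.0011), and BCL2 by 0.86 (adjusted p = 5.0e-04). For IL7R and HEXIM1 the lines differed by -0.23 and -0.25 (adjusted p = 0.709 and 0.472). IL1B fell by 2.67 in MHH-CALL4 and differed by -0.34 in MUTZ-5, where it was low under both treatments. GCSAM, a signalling adaptor of germinal centre cells, fell by 1.71 in MHH-CALL4 and differed by 0.33 in MUTZ-5 (adjusted p = 0.022), and MPO fell by 2.47 and 0.48. The potassium channel KCNQ5 and the Wnt receptor LGR5 fell by 1.66 and 1.78 in MHH-CALL4 and differed by 0.20 and -0.016 in MUTZ-5, where they lay at 6.52 and 5.64 under JQ1, near the low end of the scale. ITGA8, CYP26A1, GJB6, CHI3L2 and the GABA receptor subunit GABRG3 fell further in MUTZ-5, by differences of -2.43, -2.13, -1.98, -1.89 and -1.79. These 5 genes lay between 5.74 and 6.72 in MHH-CALL4 under JQ1, also near that end. SERPINI1 rose further in MUTZ-5 by 1.61 (adjusted p = 0.0050), and its rise in MHH-CALL4 by 0.63 was lost without MHH-CALL4 DMSO replicate 3 (adjusted p = 0.0668), without JQ1 replicate 1 (adjusted p = 0.0785) and after cyclic loess (0.56, adjusted p = 0.0798). In MHH-CALL4 it lay at 5.21 and 5.84 under DMSO and JQ1, also near the low end, so these differences are not exact. In all, 218 genes differed, 135 with the higher effect in MUTZ-5 and 83 with the higher effect in MHH-CALL4, and 71 of them differed by at least 2-fold. Of the 218 genes 194 also differed between the lines under DMSO, as did 23.4% of all genes. Most of them thus started from unlike levels, although both comparisons use the same DMSO arrays and so share their noise. Without MUTZ-5 DMSO replicate 3 the count of genes with unlike effects was 360, and among genes at or above the median level 136. With the replicate number as a block it was 136. With the residual axis as a covariate it was 693, but this axis came from the model's own residuals, which by construction lowers the residual variance.

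As lists, 5 groups had the more negative effect in MHH-CALL4 by camera with the preset correlation. Of these fry called B lineage transcription factors and MHC class II genes (adjusted p = 0.0405 for both). It did not call DNA replication genes (fry adjusted p = 0.169), MYC targets (0.267) or polymerase I and III genes (0.328), nor immediate early genes (0.166). It also called the BET inhibitor markers (fry adjusted p = 0.0401), which camera did not. DNA replication genes differed by a median of 0.17 log2 (camera adjusted p = 1.4e-05; adjusted p = 0.891 with an estimated correlation), although 0 of 34 members passed alone, also adjusted over the list alone. MHC class II genes differed by 0.28 (adjusted p = 3.6e-04; adjusted p = 0.887 with an estimated correlation), and CIITA and HLA-DMB passed (3 adjusted over the list alone). B lineage transcription factors differed by 0.13 (adjusted p = 0.0011; adjusted p = 0.887 with an estimated correlation), with 5 of 34 members past the test, among them IKZF1 (1.25) and IKZF2 (0.98), and 13 higher and 5 lower adjusted over the list alone. MYC targets differed by 0.13 (adjusted p = 0.0024) and polymerase I and III genes by 0.18 (adjusted p = 0.03), with 0 members of either past the test, also adjusted over the list alone, and an adjusted p = 0.942 for both with an estimated correlation. Immediate early genes differed by -0.12 (adjusted p = 0.0016; adjusted p = 0.887 with an estimated correlation), with 1 member higher and 2 lower (2 and 6 adjusted over the list alone). Among genes at or above the median level the calls for MYC targets, polymerase genes and B lineage factors were lost (adjusted p = 0.107, 0.281 and 0.0505) with medians of 0.14, 0.16 and 0.15. Without MUTZ-5 DMSO replicate 2 the medians of MYC targets, polymerase genes and B lineage factors were 0.084, 0.10 and 0.085, and without DMSO replicate 3 that of polymerase genes was 0.27. Without MHH-CALL4 JQ1 replicate 3 the immediate early median was -0.079. The polymerase call was also lost with extended summaries (adjusted p = 0.125), with which the histone list passed (-0.13, adjusted p = 0.0209). It was lost without MHH-CALL4 DMSO replicate 1 or JQ1 replicate 3, and without MUTZ-5 DMSO replicate 1 or 2 or JQ1 replicate 1 (adjusted p from 0.0595 to 0.233). The lists of erythroid and megakaryocyte markers and of p53 targets each passed in at least 1 alternative (lowest camera adjusted p = 0.0183 and 0.0147).

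Under DMSO the lines differed at baseline in genes of many kinds. The transcription factor ETV6 was at 12.39 ± 0.038 in MHH-CALL4 and 6.80 ± 0.10 in MUTZ-5 (n = 3, limma adjusted p = 6.5e-15). GTSF1, a factor of the piRNA pathway, LGR5 and the TGF-beta receptor TGFBR2 lay at 12.61, 11.44 and 12.27 in MHH-CALL4 and at 5.69, 5.66 and 6.70 in MUTZ-5. ALKAL2, a ligand of the receptor ALK, the adaptor FYB1 and the meiotic gene SYCP2 lay at 5.32, 6.12 and 4.81 in MHH-CALL4 and at 11.46, 12.11 and 10.75 in MUTZ-5. The lower of these levels lie at or near those of olfactory receptor genes, whose array means were 5.68 to 5.94, so the size of the differences is not exact. Over the alternatives the difference ranged from -7.08 to -4.61 for GTSF1 and from 2.11 to 6.36 for ALKAL2, smallest with extended summaries. MYC and IL7R differed by 0.13 and -0.22 (adjusted p = 0.198 and 0.197). In all 3330 genes differed, 1695 higher and 1635 lower in MUTZ-5, and after median centring 1462 were higher and 2039 lower, and after cyclic loess 1789 and 2009. Differences of at least 2-fold were found in 568 genes, 279 higher and 289 lower in MUTZ-5. Groups did not overlap in 36.2% of genes, where chance gives 10%.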

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

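Chosen only after the result was seen were the division by list of the tests on rescaled MUTZ-5 effects and on the 2 arrays, the division by line and size of change and the bound of 2 SE in the tests of the excess of decreases, the demand there that median centring and cyclic loess both remove it (at first either, which centring in MUTZ-5 would have met), the correlations in the splits, and both tests on the axis of residual variation. Results stand here because the JQ1 effect differed between the lines in a direct test, or because a signal lay in data the comparisons did not use. Of 179 named genes 41 differed, 26 with the higher and 15 with the lower effect in MUTZ-5. Over all genes 218 of 14232 (1.5%) differed. Some named genes were chosen as the largest differences between lines or the largest changes in a line, so their higher share follows in part from the choice.

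MUTZ-5 effect minus MHH-CALL4 effect (log2) was negative for ITGA8 (-2.43), CYP26A1 (-2.13), GJB6 (-1.98), CHI3L2 (-1.89), GABRG3 (-1.79), ALKAL2 (-1.58), H4C8 (-1.23), TNFRSF17 (-1.05), H2BC11 (-1.003), CD34 (-0.995), CCND1 (-0.96), VPREB3 (-0.90), DUSP6 (-0.84), PRDM1 (-0.66) and SLC7A5 (-0.46). The difference was positive for CIITA (0.58), HLA-DMB (0.61), ETV6 (0.65), MYC (0.73), CA6 (0.77), ERG (0.83), BCL2 (0.86), TARS3 (0.86), FGD6 (0.96), IKZF2 (0.98) and LYZ (1.02). It was also positive for H2AJ (1.04), ABCA9 (1.04), SLC2A5 (1.05), GSDME (1.18), PECAM1 (1.23), IKZF1 (1.25), CMAHP (1.31), CTSG (1.32), SCIMP (1.35), SERPINI1 (1.60), LGR5 (1.77), KCNQ5 (1.87), MPO (1.99), GCSAM (2.04) and IL1B (2.34). The median difference over list members was 0.28 for MHC class II genes, 0.18 for polymerase I and III genes, 0.17 for DNA replication genes, 0.13 for MYC targets, 0.13 for B lineage transcription factors and -0.12 for immediate early genes. Of 111661 clusters outside the core set, which the comparisons did not use, 1413 changed with JQ1 in MHH-CALL4 (451 higher, 962 lower) and 443 in MUTZ-5 (104 higher, 339 lower). Their median level was 6.13 log2, and with no negative controls in the files the signal over background is not known.

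For the difference between lines, 8 of 100 splits of the arrays within lines gave at least as many genes as the real 218, so by this count chance could not be excluded. In all 7 others the correlation between lines was negative (-0.767 to -0.26), so with labels turned in 1 line the shared JQ1 effect enters the difference; these splits are no clean reference and the count does not decide. The highest other count, 5136, came from the split that swaps all labels in 1 line. This swap turns the difference into the average effect, so its count is that of the real average JQ1 effect. At least as many lists as the real 6 were called in 41 of 100 splits, with at most 14 in another, and in 31 of the 40 others the correlation was negative, so that count does not decide either. For the average effect and the shared calls 1 of 100 splits, the real one, gave as many genes (5136 against at most 2664, and 2324 against at most 21). For the correlation between lines it was 1 of 100 too (0.767 against at most 0.631). This argues against a chance split of these arrays, at the smallest share that 100 splits can give. It does not cover chance between cultures, since the labels do not say whether the samples were separate cultures. Within a line and under DMSO there are 10 splits, too few for a share under 0.05. There the real and highest other counts were 4057 and 0 genes in MHH-CALL4, 3138 and 0 in MUTZ-5, and 3330 and 0 under DMSO. For changes of at least 2-fold they were 286 and 0, and 230 and 0. For lists they were 13 and 11 in MHH-CALL4 and 9 and 9 in MUTZ-5, where 3 of the 10 splits, the real one included, called as many.

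More genes were called lower than higher after JQ1 in both lines, also among changes of at least 2-fold. In MHH-CALL4 decreases were 61.4% of calls without the 2 arrays farthest along the residual axis and 67.7% among genes at or above the median level. Of changes of at least 2-fold they were 75.9% and 83.1%, and 75.6% or more after median centring or cyclic loess. These values argue against the 2 arrays and genes near the floor, and for the changes of at least 2-fold against shifts between arrays. The argument is a rough one. The jackknife SEs (1.51 over all calls, 6.22 at 2-fold), also those of MUTZ-5, came from leaving out arrays as deposited with all genes, not from these settings. Leaving out 1 array in MHH-CALL4 gave 63.9% to 65.8%, all above the 61.5% of all arrays, so 1.51 does not measure the spread of that share. In MUTZ-5, where leaving out 1 array gave 47.3% to 68.2%, the 2 arrays may account for the excess over all calls (47.6% without them), and genes near the floor cannot be told apart (56.8%, SE 14.8). Among changes of at least 2-fold in MUTZ-5 none of the 3 can be excluded, with 70.8% after centring, 65.1% without the arrays and 74.8% among genes at or above the median level (SE 13.9). The authors' quantile normalization cannot be told apart from an effect of JQ1, untested, over all calls: neither scaling undoes it, and decreases were 51.5% and 48.5% after centring, which moves all genes of an array alike, and 56.0% and 55.6% after loess.

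DNA replication genes, B lineage transcription factors and MHC class II genes had the more negative effect in MHH-CALL4, as had MYC targets and polymerase genes. A larger response of all genes in MHH-CALL4 was tested by dividing MUTZ-5 effects by the ratio of the spreads over all genes (0.890). The ratio over genes called on average was 0.913 and was not tried. After the division 3 of the first 3 lists were still called, which argues against a larger response for these. It may account for the MYC targets, whose median went from 0.13 to 0.055 (camera adjusted p = 0.4). For the polymerase genes it cannot be told apart, since the call ended (camera adjusted p = 0.232) with the median at 0.16 against 0.18 before. The 2 arrays farthest along the residual axis are argued against for the 4 lists called without both and without each, but cannot be told apart for the polymerase genes, called without both (adjusted p = 0.0482) and not without MHH-CALL4 JQ1 replicate 3 (adjusted p = 0.233). With chance open, and no list called with an estimated correlation, a difference in the biology of the lines stays an untested hypothesis.

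Arrays of 1 group differed along an axis on which dim genes rose together, with MUTZ-5 DMSO replicate 3 and MHH-CALL4 JQ1 replicate 3 at its ends. The axis was turned so that genes below the median level load positively. This sets the direction for dim genes such as olfactory receptor genes, but not the size of their loading. The 220 olfactory receptor genes, which none of the candidate cell types expresses, had a median loading of 0.22, above the upper quartile of all genes (0.18). This size argues against cells of another type as the whole cause. Markers of T and NK cells (0.26), myeloid cells (0.21), erythroid cells (0.38) and stroma (0.23) loaded the same way. Most of these loaded further than olfactory receptor genes, so a part played by such cells cannot be excluded. The correlation of loading with level across genes was -0.42, and its negative sign follows from the way the axis was turned. Array or RNA quality could give a correlation of this size, but with no measure of either it cannot be told apart from other sources. No biological explanation was tested.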

How the results depend on the processing

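Leaving out the 2 arrays farthest along the residual axis, and using that axis as a covariate, were chosen after the data were seen; the other alternatives were fixed before. Of 28 list calls over the 3 comparisons 28 were lost with an estimated correlation, and 13 in at least 1 other alternative; 0 changed sign of the median after median centring or cyclic loess. Neither scaling moved the median JQ1 effect of all genes by more than 0.0457 log2. Of 250 calls of named genes 14 were lost in some alternative. Over all alternatives 4517 values of named genes kept their side of the threshold, 40 fell short of it, 11 came to pass it and 2 reversed. For lists these numbers were 1344, 54, 30 and 0. A reversal was counted only where the gene or list was called with or without the alternative. Values called in neither could change sign, as BRD3 did in MHH-CALL4 (-0.031 to 0.073) and the DNA replication median in MUTZ-5 (-0.056 to 0.031). The number of arrays, and a signal over background that the files do not give, limit what dim genes can show.

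Leaving out each array in turn gave 2947 to 3485 called genes in MHH-CALL4 and 2310 to 3175 in MUTZ-5, 284 to 302 and 209 to 236 of at least 2-fold, and 1837 to 2291 shared genes. The correlation between lines ranged from 0.713, without MUTZ-5 DMSO replicate 3, to 0.777. The average effect gave 4510 to 5231 genes, the lines under DMSO 2640 to 3699, and the difference between lines 157 to 360, the highest without MUTZ-5 DMSO replicate 3. Lists called numbered 11 to 13, 10 to 10 and 5 to 7. Without the 2 arrays there were 4339 genes in MHH-CALL4 and 3598 in MUTZ-5, 2481 shared, 306 for the difference and 4342 under DMSO. For these counts the cause was not tested. With the residual axis as a covariate the difference between lines gave 693 genes. The axis came from the residuals of this same model, so the effects stayed as they were (correlation between lines 0.767). It took up 43.9% of the residual variance, and more calls follow from that construction. The 693 genes are therefore no independent count.

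The labels do not say whether replicates of the same number were paired. Residuals of such arrays correlated at 0.299, 0.0703 and 0.229 in MHH-CALL4 and at -0.174, -0.213 and -0.436 in MUTZ-5. In MHH-CALL4 the DMSO arrays of replicates 1 and 3 correlated best with the JQ1 array of their own number, and that of replicate 2 did not. No MUTZ-5 array did so. A pairing in MHH-CALL4 therefore stays open. With the replicate block 3415 genes were called in MHH-CALL4, 2598 in MUTZ-5, 1916 in both, 136 for the difference between lines, 4560 on average and 2990 under DMSO. The replicate block takes residual degrees of freedom. With it 12, 9 and 6 lists were called; the list no longer called in MHH-CALL4 was that of interferon-stimulated genes (adjusted p = 0.0556). CDKN1A in MUTZ-5 had an adjusted p = 0.0656.

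Array weights gave 6667 genes in MHH-CALL4, 9335 in MUTZ-5, 4812 in both, 3533 for the difference, 9186 on average, 8724 under DMSO and a correlation of 0.725. The weights' estimation stopped before it converged and gave MUTZ-5 DMSO replicate 1 a weight of 17.2, so these values are not reliable. With them PPBP in MUTZ-5 turned to -0.30 (0.11 and not called otherwise). With extended summaries 144 genes changed at least 2-fold in MUTZ-5, and RPL35 in MHH-CALL4 turned to -0.15 (1.09 in the core form); the slope of extended on core effects was 0.862 and 0.856. Genes at or above the median level, fewer genes by construction, gave a correlation of 0.878, 136 genes for the difference, and 8 lists in MHH-CALL4 and 3 for the difference. All core clusters gave a correlation of 0.694. The estimated correlation gave 0 lists in each comparison, and fry, which does not compare a list with other genes, gave 21, 15 and 3. Except where the construction shows it, the cause was not tested.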

Other observations

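No test in this part was chosen after its result was seen. Some gene groups outside the comparisons above had called members without a camera call for the list in the core form. Of the lists in this part fry called 3 lower in both lines (MHH-CALL4, then MUTZ-5). These were Ph-like genes (fry adjusted p = 4e-05 and 0.00144), NF-kappaB targets (0.00341 and 0.00234) and ribosomal proteins (0.00544 and 0.00624). Of 20 glycolysis genes 9 fell and 4 rose in MHH-CALL4 (9 and 5 adjusted over the list alone; camera adjusted p = 0.386) and 8 fell and 3 rose in MUTZ-5 (8 and 4; adjusted p = 0.338). Hexokinase HK2 fell by 0.62 and 0.78 log2 while the aldolase ALDOC rose by 0.85 and 0.83. Of 19 cholesterol and lipid synthesis genes 6 fell and 3 rose in MHH-CALL4 (8 and 3 adjusted over the list alone; adjusted p = 0.376) and 4 fell and 1 rose in MUTZ-5 (6 and 4; adjusted p = 0.933), with FASN at -0.60 and -0.64 and TM7SF2 at 1.22 (0.74 with extended summaries) and 0.85. Of 13 Ph-like classifier genes 5 fell and 1 rose in MHH-CALL4 and 3 fell and 1 rose in MUTZ-5, also adjusted over the list alone (adjusted p = 0.162 and 0.651), with MUC4 at -0.98 and -1.29. Of 24 ribosomal protein genes 6 fell and 2 rose in MHH-CALL4 (7 and 2 adjusted over the list alone; adjusted p = 0.376) and 4 fell in MUTZ-5, also adjusted over the list alone (adjusted p = 0.293), with RPS14 at -0.98 and -0.71 (-0.47 and -0.36 with extended summaries). With extended summaries the ribosomal list passed in both lines, with medians of -0.19 (adjusted p = 0.00291) and -0.24 (adjusted p = 0.000475) against -0.060 and -0.049 in the core form.

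Of 25 p53 targets 8 fell and 7 rose in MHH-CALL4 (9 and 9 adjusted over the list alone; adjusted p = 0.616) and 7 fell and 5 rose in MUTZ-5 (8 and 5; adjusted p = 0.72). The death receptor FAS fell by 1.43 and 1.34 log2, and by 0.89 and 0.84 with extended summaries. Of 23 NF-kappaB targets 8 fell and 3 rose in MHH-CALL4 (9 and 3 adjusted over the list alone; adjusted p = 0.376) and 6 fell and 2 rose in MUTZ-5 (7 and 3; adjusted p = 0.14), with the cytokine LTA at -1.66 and -1.20 and CFLAR at -0.62 and -0.55. Of 32 mitosis genes 5 rose and 3 fell in MHH-CALL4 (4 and 3 adjusted over the list alone; adjusted p = 0.399) and 7 rose and 4 fell in MUTZ-5 (7 and 5; adjusted p = 0.285), with PTTG1 at 0.44 and 0.45 and FOXM1 at -0.47 in MHH-CALL4. Without MUTZ-5 JQ1 replicate 3 the mitosis list passed in MUTZ-5 (adjusted p = 0.0408).

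Genes that neighbour each other may respond together, and this was tested on the average JQ1 effect. Over 12010 adjacent pairs of 14200 genes the correlation was 0.036, inside the range of 1000 shuffles of gene order within chromosomes (-0.0076 to 0.055, mean 0.024), so no shared response of neighbours was found.

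Genes may fall further in the line that expresses them more. With the DMSO arrays split between the measures, the difference in level and the difference in JQ1 effect correlated across genes at -0.29, -0.30 and -0.10. The weakest of these, -0.10, lies just past the bound of -0.1 set for it, and among genes at or above the median level the values were -0.18, -0.21 and -0.068. The values fit this hypothesis weakly, and a gene near the floor in 1 line has no room to fall there, which gives the same pattern.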
